A study of Caenorhabditis elegans with 3 samples.

How the data were processed

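Expression was measured on 3 two-colour arrays, each with RNA of 1 mid-L3 hermaphrodite prep in the second channel and the mixed wild-type reference in the first, per the labels. The deposited table holds log2 ratios, 1 per probe and array, made by the authors. Scanner, background correction, normalization and dyes are not given in the sources used here. That the values are log2 was read from the table: 2 to the power of a value was a multiple of 0.001 (within 0.001 of a whole number of thousandths) for 97.86%, 97.03% and 98.33% of values in preps 1, 2 and 3, against 0.4025%, 0.3573% and 0.3272% with base e. The deposited medians were 0.02715, -0.06643 and 0.03281 and the deposited means -0.01034, 0.003022 and -0.006652, so the arrays had been centred near 0 by the authors, in a way that stays unknown. The direction of the ratio is not given either. Signs were kept as deposited. The labels write mid-L3 before the reference but state no numerator. The rule fixed beforehand named a likely direction only if both of its lists shared a sign on every array. It was not met, so it names none. The oocyte and eggshell values given in the results, weighed after they were seen, argue against reference over mid-L3. With the probe listed for both *vit-1* and *vit-2* counted in, which the rule on names excludes, the vitellogenin medians were -2.05, -1.905 and -2.697. No signal intensity, background or flag was used here, so dim spots could not be told from bright ones.

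Of 20000 probes, 15655 had 1 gene symbol in an old platform annotation, 198 had several and 4147 had none listed. Symbols were updated through the Entrez gene identifier with the RefSeq gene table of assembly WBcel235, which matched 15569 of the one-gene probes and left 86 with the annotation's own symbol. Chromosomes come from that table, and no coordinates were used. No gene was named from a probe with several symbols. Such probes and those with no listed gene were kept as 4139 unnamed features, which may include control spots.

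Each array was centred on the median of its log2 ratios over the 19512 probes with a value on all 3 arrays. Probes of a gene were averaged. This concerned 420 genes, of which 14 had probe means more than 1 log2 unit apart. The mean log2 ratio of each feature was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, eBayes without a trend, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The test sets 3 preps against one reference RNA and leaves out the reference's spread. Gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. Lists of at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 17 lists. An estimated correlation refers the statistic to the 2 residual degrees of freedom of 3 arrays. Lists overlap where a gene belongs to more than 1. The X chromosome was tested in the same way against the autosomes, over 14864 genes with a chromosome.

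The rule for named genes took the 6 highest and 6 lowest named genes past the threshold with the same sign on all arrays, and from each list the 2 members with the largest absolute mean among such genes, or the farthest member where none passed. Genes outside the rule are said to be named after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

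The fit was tested on simulated data for the comparison of mid-L3 with the reference, with 19075 features, normal errors with the moderated variance of each and a changed subset. All 100 features changed by 2 log2 units and 86 of 100 changed by 1 were recovered, and 18 of 204 calls were of unchanged features. In a simulation of 18 lists of 40 genes with 1 list moved by 0.5 and independent errors, camera with the preset correlation called that list and 0 others. With an estimated correlation the moved list was missed, at an adjusted p of 0.213. As the simulated errors were independent, this says nothing on false calls among correlated genes. The estimated correlations of the called lists were 0.2335 for major sperm proteins, 0.09643 for ribosomal proteins, 0.08771 for molting, 0.07618 for spermatogenesis, 0.06658 for muscle, 0.06099 for oocyte and eggshell genes, 0.03031 for neurons and -0.01634 for meiotic prophase, so all but the last exceed the preset value, and their calls with it may be too many.

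Alternatives were other centrings and scalings, at least 2 arrays per probe, every probe on its own, array weights, robust moderation, a minimum of 2-fold, fry and an estimated correlation for lists, and leaving out each prep. Centring within each sector of 25 by 25 probes, centring on a local median of 11 by 11 spots, and testing named features only were added after seeing the data. The 32 sectors were inferred from the periodicity of the values along the probe order. The array titles hold a different date for every array, so a batch cannot be told apart from a prep. The labels call the RNA both total RNA and mRNA.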

Results

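RNA from mid-L3 hermaphrodites of *Caenorhabditis elegans* was compared with a common wild-type reference RNA that the labels call mixed, without saying what was mixed. L3 is the larval stage before the last larval stage, when the hermaphrodite germline is still small and holds no mature sperm or oocytes. There were 3 two-colour arrays, 1 for each of 3 separate mid-L3 preps, and every array carried the same reference in its other channel. Each array gave a log2 ratio for most of its 20000 probes. Prep 1 lacked a value at 372 probes, prep 2 at 126 and prep 3 at 137. The preps were separate by their labels, but the labels do not say whether they came from separate cultures. The p-values therefore measure the spread between these 3 preps, moderated in limma towards the spread of all features. The prior held 9.8 degrees of freedom, against 2 from the arrays. The variance behind a limma p-value thus comes mostly from other features, while the errors quoted below are each gene's own. The number of arrays limits the precision, and the reference's own spread is not part of it.

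Which channel is the numerator of the ratio is not stated. A rule fixed before the data were examined required the major sperm proteins and the vitellogenins, products of spermatogenesis and of the adult intestine, to share one sign on every array before a direction was named. The 30 major sperm protein genes had median log2 ratios of -2.53, -2.15 and -2.69 on the arrays of preps 1, 2 and 3. The 3 vitellogenin genes with a probe of their own had medians of 0.28, -0.33 and 0.43, so the rule was not met and names no direction. Within that list *vit-2* lay at -5.52 ± 0.78 (SD, n = 3, as for all errors here), *vit-5* at 0.52 ± 0.68 and *vit-6* at 0.14 ± 0.41. Other values, weighed after they were seen, argue against a ratio of reference over mid-L3. Of 33 oocyte and eggshell genes, which were not part of the rule, 28 were negative and 0 positive past the threshold. Their medians were -2.525, -2.283 and -2.615 in preps 1, 2 and 3, though mid-L3 animals hold no mature oocytes. The results are given as positive or negative ratios, with the sign as deposited.

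The first comparison asked which genes differed between mid-L3 and the reference. Of 19075 features tested, of which 14936 carried a gene name, 2583 had a positive and 2624 a negative mean ratio past the threshold (limma, Benjamini-Hochberg adjusted). The highest ratio among named genes was that of *irg-5*, an infection response gene, at 5.51 ± 1.01, a 45.6-fold difference. It was followed by *ugt-22*, a UDP-glucuronosyltransferase gene, at 4.35 ± 0.57, *ZK1025.3* at 4.19 ± 0.76, the cathepsin B-like protease gene *cpr-5* at 3.84 ± 0.36, *F09B12.3* at 3.74 ± 0.44 and *dod-19* at 3.70 ± 0.20. The lowest was that of the yolk protein gene *vit-2*, a 45.7-fold difference. Next were *ZK813.3* at -5.51 ± 0.92, *ule-3* at -5.19 ± 0.58, *D1054.10* at -5.18 ± 0.34, *ule-4* at -5.04 ± 0.24 and *ule-5* at -4.63 ± 0.36, the *ule* genes being named for expression in the uterine lumen. The adjusted p of these 12 genes ranged from 7.99538e-08 to 4.85144e-07. Of the 5207 features past the threshold, 5171 had the same sign on all 3 arrays. A call needs a mean far from 0 on these same arrays (smallest absolute mean 0.528), so this count follows largely from the selection. Among all features 54.6% had the same sign on all 3. As the arrays share one reference in one channel, part of this share may come from the reference or from the probes.

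**Figure D1:**
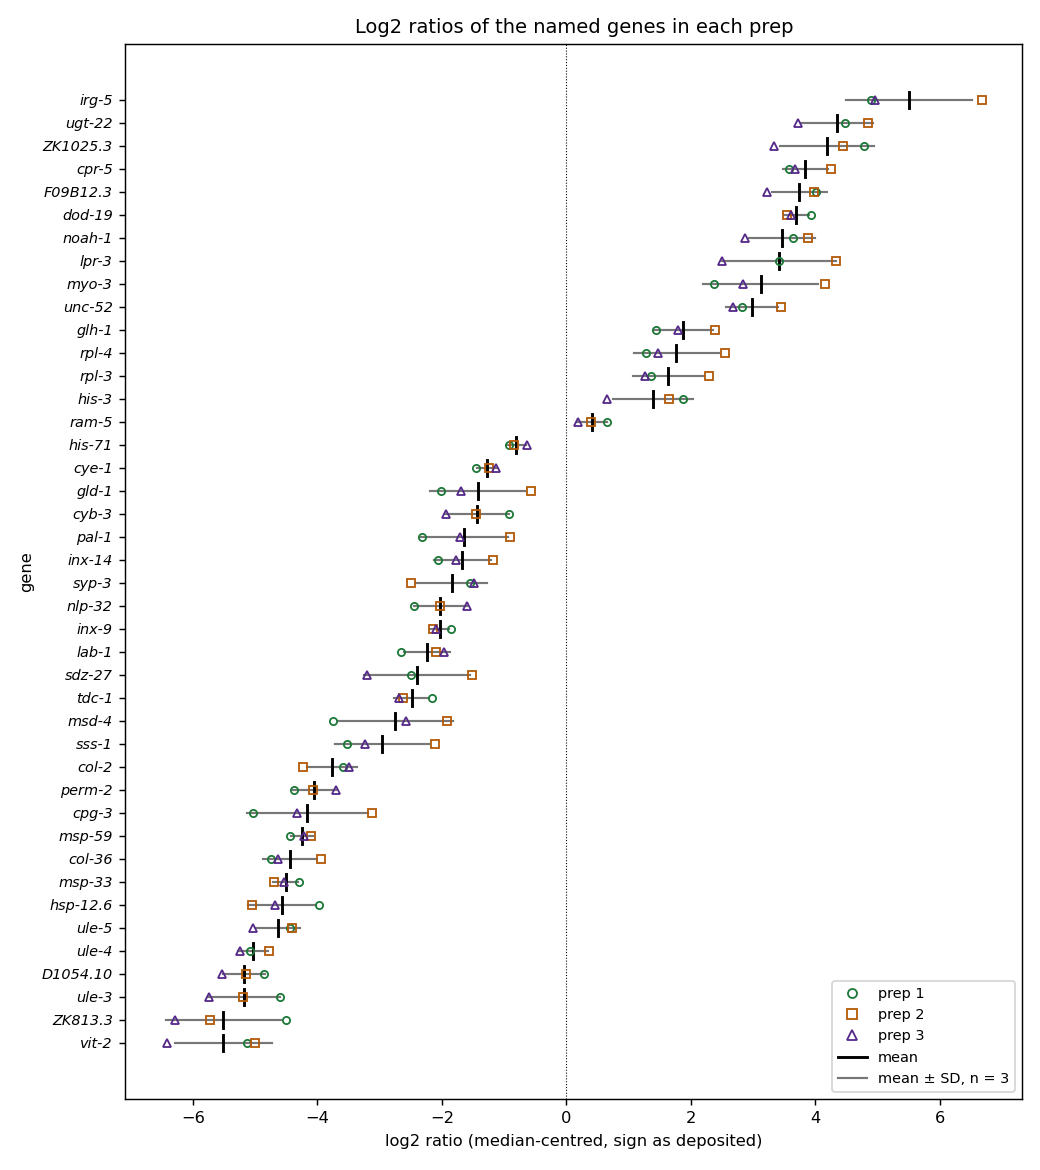
Log2 ratio (x axis, median-centred, sign as deposited) of each named gene (y axis) in preps 1 to 3 (circles, squares, triangles), with the mean as a black tick and the SD over the 3 preps as a grey line. Except for *ram-5*, at 0.41 ± 0.24 and not past the threshold, the genes passed it with all 3 preps on one side of 0, from *vit-2* at -5.52 to *irg-5* at 5.51.

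Genes of sperm and oocyte formation had negative ratios. Of 30 major sperm protein genes, which encode the cytoskeletal and signalling protein of nematode sperm, 29 were negative past the threshold over all genes tested and 29 adjusted over the list alone, with a median of -2.43, a 5.41-fold difference. The lowest were *msp-33* at -4.51 ± 0.20 and *msp-59* at -4.25 ± 0.17. These genes are near-identical in sequence, so their spots may share targets and the members are not independent. This list also served the rule on the sign and is no independent evidence of direction. Of 49 other spermatogenesis genes, 22 were negative and 1 positive (24 and 1 adjusted over the list alone), with a median of -0.48. Examples are *sss-1* at -2.96 ± 0.75 and *msd-4* at -2.75 ± 0.93. The positive gene, *fog-3* at 0.73 ± 0.55 (named after its value was seen), is known to act in the choice of the sperm fate, and it did not pass without prep 2 or without prep 3. Of 33 oocyte and eggshell genes 28 were negative, over all genes and adjusted over the list alone, with a median of -2.48, a 5.58-fold difference. The lowest were *cpg-3*, for a chondroitin proteoglycan, at -4.16 ± 0.97 and *perm-2*, for an eggshell permeability factor, at -4.05 ± 0.34. The 3 lists lay below the other genes in the camera test with a preset inter-gene correlation, with adjusted p of 4.709e-27 for the major sperm proteins, 1.62e-06 for spermatogenesis and 4.525e-23 for oocyte and eggshell genes. With an estimated correlation these were lost, at adjusted p = 0.1953, 0.2419 and 0.1953. That form rests on 2 residual degrees of freedom. In simulation it also missed a moved list of independent genes (camera adjusted p = 0.213). Its losses, here and below, therefore cannot decide whether correlation between genes accounts for a shift.

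Genes of meiotic prophase were also negative, while germ granule genes went both ways. Of 23 meiotic prophase genes 13 were negative (15 adjusted over the list alone), with a median of -1.03, a 2.05-fold difference. The lowest were *lab-1*, which protects the long arms of meiotic chromosomes, at -2.24 ± 0.37, and *syp-3*, a synaptonemal complex gene, at -1.84 ± 0.57. The camera adjusted p was 3.745e-07, lost with an estimated correlation at adjusted p = 0.1953. The estimated correlation of this list was -0.01634, below the preset 0.01, so correlation between its genes does not account for that loss. Of 26 germ granule and germline proliferation genes, 6 were positive and 7 negative (8 and 7 adjusted over the list alone), with a median of -0.36 and no shift by camera (adjusted p = 0.6098). The negative genes numbered 4 without prep 1 and 4 without prep 3, and the median was -0.15 without prep 2. *glh-1*, which encodes a Vasa-like helicase of germ granules, was at 1.87 ± 0.48, and *gld-1*, a translational repressor of the germline, at -1.43 ± 0.76. Further members, named after their values were seen, were *glh-2* at 1.29 ± 0.24, *prg-1* (a Piwi protein gene) at 1.04 ± 0.52 and *pgl-3* at -0.74 ± 0.14. Of 52 genes of early zygotic transcription in the embryo 8 were negative (5 adjusted over the list alone), led by *sdz-27* at -2.40 ± 0.85 and *pal-1* at -1.65 ± 0.71. The list's shift of -0.23 did not pass (camera adjusted p = 0.05226), and it passed under 7 of the alternatives tried, among them leaving out prep 2 (adjusted p = 0.02534). *pal-1* is also known as a maternal transcript.

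Muscle and ribosomal protein genes had positive ratios. Of 41 muscle genes 29 were positive (33 adjusted over the list alone), with a median of 1.31, a 2.49-fold difference. *myo-3*, a body wall myosin heavy chain gene, was at 3.12 ± 0.92 and *unc-52*, the perlecan gene of the muscle basement membrane, at 2.99 ± 0.41. *unc-54*, the major body wall myosin heavy chain gene, did not follow, at -0.08 ± 0.34 (named after its value was seen). Of 61 ribosomal protein genes 41 were positive (50 adjusted over the list alone), with a median of 0.78, a 1.72-fold difference, led by *rpl-4* at 1.77 ± 0.68 and *rpl-3* at 1.64 ± 0.57. The camera adjusted p was 2.041e-16 for muscle and 3.817e-14 for ribosomal proteins. With an estimated correlation these were lost, at adjusted p = 0.1953 and 0.209.

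Cuticle genes split. Of 120 genes of molting and the apical matrix, 34 were positive and 11 negative (38 and 11 adjusted over the list alone), with a median of 0.30. *noah-1*, a zona pellucida domain gene of the apical matrix, was at 3.47 ± 0.53 and *lpr-3*, a lipocalin gene, at 3.42 ± 0.92. The list lay above the other genes by camera (adjusted p = 0.000423), lost with an estimated correlation at adjusted p = 0.4562, and without prep 2 its positive genes numbered 19. Of 151 cuticle collagen genes, 50 were positive and 36 negative (54 and 39 adjusted over the list alone), and the list as a whole had no shift past the threshold (0.16, camera adjusted p = 0.1897). The shift was 0.02 without prep 2, and without prep 3 it passed at 0.27 (adjusted p = 0.01269). As p-values from 2 arrays were not comparable with those from 3, this pass may not be due to prep 3. The extremes by absolute ratio were *col-36* at -4.45 ± 0.43 and *col-2*, a collagen gene known for its use in dauer larvae, at -3.77 ± 0.40. Of the 16 collagen genes of the list known by their mutant phenotypes (*dpy*, *sqt*, *rol*, *bli* and others), a split made after the values were seen, 12 were positive and 1 negative. Among the 135 *col* genes, 38 were positive and 35 negative. Named after their values were seen, *sqt-1* was at 3.18 ± 1.45, *dpy-8* at 3.08 ± 0.60, and the adult-specific *col-19* at -2.21 ± 0.16.

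**Figure D2:**
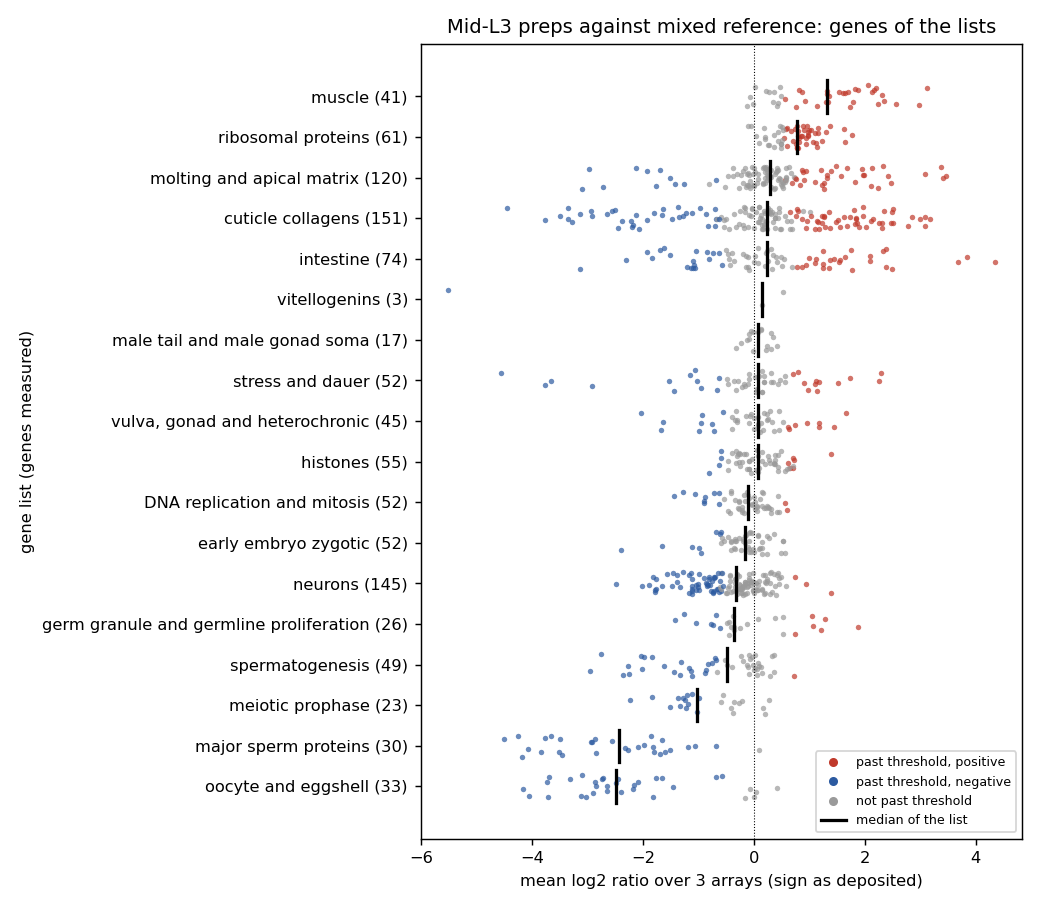
Mean log2 ratio over the 3 arrays (x axis, sign as deposited) of every measured gene (points) of the 18 gene lists (y axis, number of genes in brackets), with the list median as a black bar and genes past the threshold in red (positive) or blue (negative). Oocyte and major sperm protein genes lie lowest, with medians of -2.48 and -2.43, muscle genes highest with a median of 1.31, and collagens spread from -4.45 to 3.18.

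The neuron list leaned to negative ratios of smaller size, mostly in its peptide genes, and 88 of its 145 genes passed in neither direction. Of 145 genes, 54 were negative and 3 positive (55 and 4 adjusted over the list alone), with a median of -0.32. The lowest were *tdc-1*, the tyrosine decarboxylase gene of tyramine synthesis, which is also used in cells of the reproductive tract, at -2.49 ± 0.29, and *nlp-32* at -2.02 ± 0.43. In a split made after the values were seen, with no test of the difference, 44 of the 95 *flp*, *nlp* and *ins* peptide genes and 10 of the other 50 members were negative. The peptide genes were listed by name prefix, so genes used outside neurons may be among them. The list lay below the other genes by camera (adjusted p = 7.518e-07), lost with an estimated correlation at adjusted p = 0.209, and its negative genes numbered 34 when arrays were centred on the peak of their density. Without prep 1 its positive genes numbered 5.

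Intestinal genes went both ways. Of 74 genes 26 were positive and 19 negative (30 and 20 adjusted over the list alone), and the shift of 0.33 did not pass (camera adjusted p = 0.09907). It passed without prep 1 (0.31, adjusted p = 0.01657) and without prep 3 (0.43, adjusted p = 0.0004948). The shift without prep 1 was smaller than that with all preps, and p-values from 2 arrays were not comparable with those from 3. These passes may therefore not be due to the prep left out. Besides *ugt-22* and *cpr-5*, genes named after their values were seen were the peptide transporter gene *pept-1* at 2.38 ± 0.07, the intestinal actin gene *act-5* at 2.49 ± 0.60 and the metallothionein gene *mtl-1* at -3.14 ± 0.37. Of the 16 *spp* genes, which encode saposin-like proteins, 9 were negative and 1 positive. Among 52 stress and dauer genes 12 were positive and 12 negative, with the same counts adjusted over the list alone. The small heat shock protein gene *hsp-12.6* was at -4.56 ± 0.55, beside *col-2*. Chosen after their values were seen, *daf-9* and *daf-36*, of steroid hormone synthesis, were at 1.15 ± 0.48 and 1.52 ± 0.20. This list had no shift by camera (adjusted p = 0.9658), and its median of 0.08 and mean of -0.12 differed in sign. The median was 0.009 without prep 1, -8.455e-05 without prep 2 and 0.04 without prep 3.

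The remaining lists had no shift past the threshold. Of 45 vulval, gonadal and heterochronic genes 8 were positive and 9 negative (9 and 9 adjusted over the list alone), and the median of 0.07 and the camera direction differed in sign from the mean of -0.01. The shift ran from -0.0134 to 0.009537 when each prep was left out, and the positive genes numbered 5 without prep 2 and 5 without prep 3. The gap junction genes *inx-9* and *inx-14*, of the somatic gonad and the germline, were at -2.03 ± 0.15 and -1.67 ± 0.46, and the larval timing genes *lin-42* and *lin-29*, named after their values were seen, at 1.45 ± 0.48 and 1.18 ± 0.67. Of 52 DNA replication and mitosis genes 2 were positive and 9 negative (1 and 9 adjusted over the list alone), with 0 positive in limma when any prep was left out. The negative genes include the cyclin genes *cyb-3* at -1.44 ± 0.51 and *cye-1* at -1.28 ± 0.16. Of 55 histone genes, many of them near-identical in sequence, 6 were positive and 4 negative (3 and 1 adjusted over the list alone), with *his-3* at 1.39 ± 0.65 and *his-71* at -0.80 ± 0.15. The negative histone genes numbered 1 without prep 1, 2 without prep 2 and 1 without prep 3, and the positive ones 3 without prep 2. Of 17 genes of the male tail and male gonad soma, 0 passed in limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. The farthest from 0 was *ram-5* at 0.41 ± 0.24. The camera adjusted p was 0.9658 for the vulval list, 0.1599 for replication and mitosis, 0.6033 for histones and 0.633 for the male list.

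Genes on chromosome X had higher ratios than autosomal genes. The question follows from the known scarcity of germline-expressed genes on X. The 2243 X genes had a mean of 0.11 against -0.04 for autosomal genes, a shift of 0.15 (camera, adjusted p = 0.02615, over this 1 test). This was lost with an estimated correlation, at adjusted p = 0.5295. Of the X genes 17.16% were positive and 9.81% negative past the threshold. The positive share was 12.78% on chromosome I, 13.63% on II, 16.73% on III, 13.63% on IV and 12.24% on V, and the negative share was 20.6% on I, 16.3% on II, 15.3% on III, 17.8% on IV and 14.03% on V. The median of X genes in prep 2 was -0.02, below those of chromosomes I, II, III and IV (0.009, 0.07, 0.09 and -0.01). Without prep 1 the shift was 0.08 (adjusted p = 0.343).

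Ratios also followed the place of the probe in the order of probes. Deviations of an array from the mean of the 3 correlated between probes 25 places apart at 0.294, 0.296 and 0.195 in preps 1, 2 and 3, against 0.193, 0.11 and 0.136 at 12 places, a period that fits 32 sectors of 25 by 25 spots. In prep 2 the first sector of every 4 had a mean median ratio of 0.32, and the other sectors -0.09. In prep 1 the first 16 sectors had a median of -0.14 and the last 16 of 0.11. Probes for chromosome X lay in the last 16 sectors except for 0.131%, those for chromosome V without exception, and all probes for chromosome III in the first 16. Within sectors, X genes exceeded the chromosome IV and V genes of the same sector by 0.144 ± 0.0251 (SE over 16 sectors), in 14 of 16 sectors, and by 0.197, 0.0712 and 0.163 in preps 1, 2 and 3. X could not be compared in this way with chromosomes II and III, which hardly share sectors with it. With sector and local centring on the array, both chosen after seeing the data, the shift over all autosomes was 0.14 and 0.10 (camera adjusted p = 0.04389 and 0.166).

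**Figure D3:**
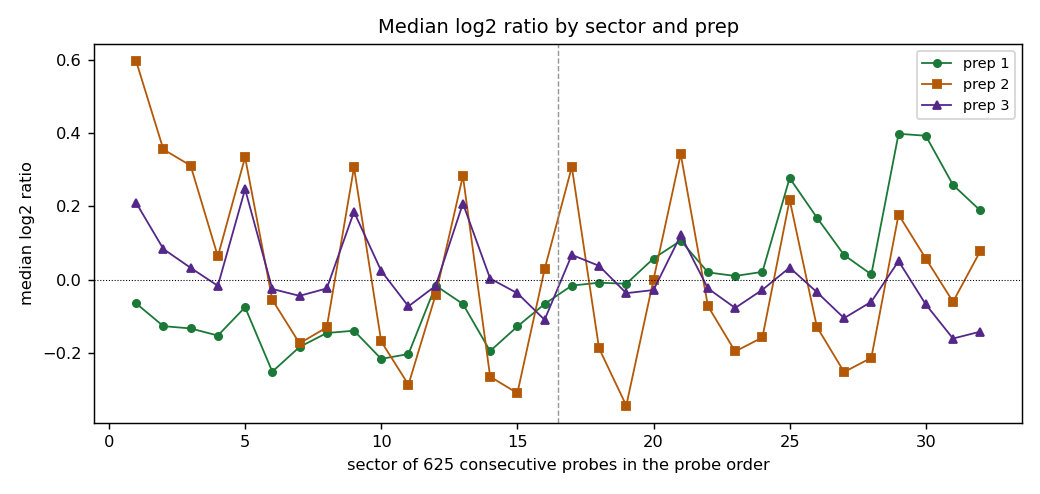
Median log2 ratio (y axis) of each of 32 sectors of 25 by 25 consecutive probes (x axis) in preps 1 to 3 (circles, squares, triangles), with a dashed line after sector 16. Prep 2 is higher in the first sector of every 4, up to 0.597, and prep 1 is higher in the last 16 sectors, up to 0.398.

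Ratios correlated between arrays, which share one reference RNA and the same probes, so part of the correlation may come from these. Across the 19075 features, which are not independent replicates, Pearson's r was 0.740 between preps 1 and 2, 0.811 between preps 1 and 3 and 0.762 between preps 2 and 3, with Spearman's rho of 0.596, 0.701 and 0.634. The median SD over the 3 preps was 0.29.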

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

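Sector and local centring and the count of named features were chosen after seeing the data. Leaving out each prep gave 1748 to 2250 positive and 1835 to 2161 negative features. A minimum of 2-fold gave 1190 and 1239, centring on the density peak gave 1654 negative features, and the other alternatives stayed within 1.5 times the counts. Under the alternatives compared feature by feature, 0 of the 5207 called features changed sign. These reuse the same arrays, and the smallest absolute ratio called was 0.528, so a change of sign was unlikely from the start. Without preps 1, 2 and 3, 73.7%, 70.2% and 69.8% of the called features passed again with the same sign, and with local centring 87.1%. Fits on 2 arrays did not estimate the spread alike. The limma adjusted p of *irg-5* was 7.405e-85, 0.001338 and 8.923e-74 without preps 1, 2 and 3, and 2.733e-07 with all. For the major sperm proteins the camera adjusted p was 3.883e-54, 2.199e-21 and 4.169e-52, and 4.709e-27 with all. P-values from 2 arrays are thus not comparable with those from 3, and calls gained or lost may not be due to the prep left out. The density peaks lay 0.0614, -0.221 and -0.00278 from the medians in preps 1, 2 and 3. With an estimated correlation the shifts of major sperm proteins (-2.54), spermatogenesis (-0.70), oocyte and eggshell (-2.21), meiotic prophase (-0.85), molting (0.41), muscle (1.29), neurons (-0.43), ribosomal proteins (0.75) and X (0.15) no longer passed, and fry, which tests the genes of a list against no change and not against the other genes, did not call spermatogenesis, molting and neurons (adjusted p = 0.05684, 0.1568 and 0.05684). Early embryo genes passed with peak centring (-0.23), scaling (-0.24), single probes (-0.24), array weights (-0.23), sector centring (-0.24), local centring (-0.22) and without prep 2, where leaving out preps gave -0.24 to -0.21. Leaving out preps gave 0.02032 to 0.2679 for collagens, which passed without prep 3 (adjusted p = 0.01269), and 0.25 to 0.43 for the intestine, which passed without preps 1 and 3 (adjusted p = 0.01657 and 0.0004948). It gave -0.007381 to 0.203 for histones and -0.0134 to 0.009537 for the vulval list, both turning sign around 0 with no call. The vulval list also turned with at least 2 arrays (0.0009255) and single probes (0.027). The X shift was 0.07754 to 0.2027 and did not pass without prep 1, nor with local centring (0.10). The mean correlation of arrays was 0.771, and 0.477 over genes under an absolute ratio of 1, whose narrower range lowers it by construction. The causes of the other differences were not tested. Of the genes named by the rule, *his-71* lost its call without prep 1 (-0.74, limma adjusted p = 0.05127). Genes named after their values were seen were not part of this check, and *fog-3* among them lost its call without prep 2 or prep 3. No paired analysis was possible because there is only 1 group. Signal over background was not used here, so what dim spots limit is unknown.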

Other observations

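The families, the genes named from them and the chromosome position tests here were chosen after the report's results were seen. The tests of the weighed patterns were written down before their own values were computed. All 145 gene classes, groups of genes with one name prefix and at least 10 tested members, were tested with camera at the preset correlation, and 15 lay above and 15 below the other genes. With an estimated correlation the smallest adjusted p over the classes was 0.76. The *msp* class, with 29 of 30 genes negative, also had this value. On 3 arrays that form therefore cannot tell classes with a shift from those without. Beyond the lists already described, the classes above included the vacuolar ATPase subunits, with 11 of 17 *vha* genes positive and 1 negative (adjusted p = 2.037e-05). *vha-12* was at 2.12 ± 0.24. The *ugt* class of UDP-glucuronosyltransferases had 27 of 63 positive and 5 negative (adjusted p = 9.978e-06), and the *abu* class had 11 of 13 positive (adjusted p = 1.938e-06). Among the mitochondrial ribosomal protein classes, 12 of 19 *mrps* genes were positive and 1 negative (adjusted p = 0.001189) and 9 of 24 *mrpl* genes were positive (adjusted p = 0.01873). Among the acyl-CoA dehydrogenases 6 of 12 *acdh* genes were positive (adjusted p = 0.007231), led by *acdh-1* at 3.68 ± 0.44.

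The classes below included the transthyretin-like genes, with 23 of 46 *ttr* genes negative and 2 positive (adjusted p = 1.938e-06) and *ttr-50* at -3.15 ± 0.26. Of the peptide classes *nlp* and *flp* were below, with 26 of 52 *nlp* genes (adjusted p = 1.5e-07) and 11 of 22 *flp* genes (adjusted p = 0.0001589) negative, and the insulin-like *ins* class did not pass, with 7 of 21 negative and 1 positive (adjusted p = 0.1885). The Skp1-related *skr* genes had 8 of 15 negative (adjusted p = 0.0006192), with *skr-5* at -2.26 ± 0.38. The *pals* genes had 8 of 22 negative and 1 positive (adjusted p = 0.004178). Members of several of these classes are similar in sequence, so their spots may not be independent, and the share of signal due to related genes stays open. The vacuolar ATPase, *ugt* and *ttr* classes also passed with local centring on the array, at adjusted p of 3.051e-05, 9.785e-05 and 1.308e-06, so position on the array is unlikely to be the whole cause of their shifts.

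A first pattern is that molting and collagen genes differed between preps more than other genes. The 271 genes of these lists had a median SD over the 3 preps of 0.468. The same number of other genes matched on absolute mean ratio gave 0.292 to 0.349 in 95% of 10000 random draws. The p over these draws was 1e-04, the smallest they can give, which argues against larger ratios simply varying more. The draws treat genes as independent, while the estimated correlation was 0.1694 for collagens and 0.08771 for molting, so this p may be too small. With local centring on the array the median SD stayed at 0.41 against 0.235 to 0.289, which argues against position on the array. Preps taken at different phases of the molting cycle, in which collagen genes are known to be switched on in turn, remain a hypothesis. A grouping written beforehand, and not itself tested, took 5 genes as early (*dpy-2*, *dpy-3*, *dpy-7*, *dpy-8*, *dpy-9*). It took 7 as late (*bli-1*, *bli-2*, *dpy-4*, *dpy-5*, *rol-6*, *sqt-1*, *sqt-3*). The early genes deviated from the late ones by up to 0.527 ± 0.276 (SE over genes, prep 3), where over 0.5 was predicted. The difference thus lies within its error of the bound. With local centring the difference in prep 3 was 0.675. Of the genes named in the prediction *dpy-10* and *dpy-13* were not among those tested. In prep 3 the mean deviation was -0.498 for the early and -1.03 for the late genes.

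A second pattern is the lower ratio of the neuron list, with a median of -0.316. The median was -0.478 for its 95 peptide genes and -0.113 for its 50 other genes, a split made after the values were seen and not tested. A bias of dim spots toward negative ratios would also lower the chemoreceptor genes, each used in few cells, if their spots were as dim. The median of 1049 such genes was 0.0329 (95% bootstrap interval 0.00956 to 0.0519), not below 0. Without intensities it is not known how dim the spots of either group were, so such a bias stays open. With local centring the shift of the list stayed at -0.43, which argues against position on the array. Differences in stage between mid-L3 and a reference that may hold other stages stay open, and no biological explanation was tested, since the design has no second group.

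The last pattern is the higher ratio of X genes. Within sectors of the array X genes exceeded those on chromosomes IV and V by 0.144, which argues against position as the whole cause. With sector centring the shift against all autosomes was 0.1362, from 0.1546, and kept its call (camera adjusted p = 0.04389). With local centring, however, the shift fell to 0.1048 and its call was lost (adjusted p = 0.166). Probes were laid out largely by chromosome, so such centring can also remove part of a true difference of X genes. A part of the shift may be due to position, but the fall cannot show whether it is. Position also remains open for chromosomes I, II and III. Germline gene content is a candidate explanation that the lists could not decide. Without them the shift kept 0.913 of its size, which the bound written beforehand would have counted against this explanation. That verdict is set aside here, since the lists hold only 108 of the 2296 named negative genes and 8 X genes. They cover too few genes to exclude it.

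In the major sperm protein, oocyte and muscle lists, 1 of 30, 5 of 33 and 12 of 41 genes passed in neither direction. Some of these had a mean ratio near 0, with signs that differed between the arrays. Examples, named after their values were seen, are *msp-38* at 0.09 ± 0.43, *cpg-2* at -0.08 ± 0.27 and *unc-54* at -0.08 ± 0.34, beside *vit-6* at 0.14 ± 0.41 among the vitellogenins. Of the 20 lowest features 9 had no gene name, and of the 20 highest 3.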
